A study of Mus musculus with 20 samples.

How the data were processed

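RNA was measured in whole ovaries of wild-type mice in 20 libraries, 4 in each of 5 groups. The groups were young (7 to 8 weeks), adult (27 to 28 weeks), adult given HEP14, aged given vehicle (73 to 74 weeks, called aged below) and aged given HEP14. The adult HEP14 group is named in the sample titles, and the design text does not describe it. Per the labels' protocols, total RNA was extracted with TRIzol and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used. The role of each tool, the genome build and the annotation are not given in the sources used here, and neither are dose, duration and strand setting.

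The deposited values are scores with no unit of expression: in the single table used, each of 17651 genes had a mean of 0 and a standard deviation of 1 over the 20 libraries. The largest absolute gene mean was 3.6e-15 and the largest deviation of a gene's SD from 1 was 2.4e-15. A difference between groups is therefore given in SD of that gene over all 20 libraries and is not a fold change, and sizes cannot be compared between genes as expression can. Levels and total reads per library cannot be had from such scores. The step by which the genes in the table were chosen is not stated. A one-way F test across the 5 groups gave a median p of 0.00381 over the genes, with 72.1% of them under 0.05, so the table may hold genes picked for differing. Counts of genes refer to the genes in this table, which were also the background of the list tests.

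Before scaling, the values had the form of a logarithm of reads plus a constant. In 4445 genes at least 2 libraries shared the lowest value within 1e-09, as genes without reads would. In these genes the ratio of 2 libraries' heights above the lowest value piled up at a limit. Over 6 pairs of young libraries, 547 ratios lay just beyond that limit on the side of equality and 159 on the other side, with the excess in 5 of the 6 pairs. The place of the limit gave the relative worth of 1 read, and from it a relative depth, with log ratios binned at a width of 0.004. Taking adult library 3 as the reference, the relative depth was 0.791 to 0.99 in the aged libraries and 0.882 to 1.16 in the libraries of the other groups. The limit was thinly marked in aged libraries 1 and 2, where the peak bin held 15 and 20 genes and the next highest 11 and 13. In aged libraries 3 and 4 the peak held 197 and 85 genes and the next highest 98 and 58. The lowest peak outside the aged group, in young library 4, held 550 genes and the next highest 179.

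Each gene was tested with limma 3.58.1 in R 4.3.3, in a fit of all 20 libraries with 1 coefficient per group, moderated statistics without a trend, and Benjamini-Hochberg adjustment within each comparison at an adjusted p of 0.05. A logarithm with a pseudocount, a filter on low values and a trend on mean expression had been planned for normalized expression values, and none of them can be applied to gene-wise scores. The design and most alternatives were fixed before the data were examined, and those added later are named as such. Gene lists, 31 in all with 563 genes in the table, were also fixed beforehand and tested with camera at a preset correlation of 0.01, with at least 5 members per list. The list tests were repeated with an estimated correlation and with fry. With an estimated correlation no list passed in any of the 6 comparisons.

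Named genes in 3 comparisons (aged against young, and HEP14 against its control at each age) were the 8 with the largest difference in each direction that passed the test and whose 4 libraries did not overlap with the other 4. In the other comparisons 4 were taken in each direction. Predicted genes, pseudogenes, ribosomal, small nuclear, small nucleolar and micro RNAs and receptor segments were left out, and transfer RNAs were not. A planned minimum level was replaced by the absence of a tied lowest value, because levels are not known. In addition, the 2 members with the smallest p of each list that passed were named, together with 26 genes of mitophagy, lysosomes, antioxidant defence and ovarian function, of which 24 were in the table. Sod1 and Cdkn2a were not analysed here. The text does not give every gene that the rule took. Of the gene identifiers, 17630 matched GENCODE release M21, and 21 did not. Coordinates are from that annotation on GRCm38 and need not be the build the authors used.

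The test was tried on simulated scores of 17651 genes with the real spread of each group and 200 changed genes, each gene drawn independently. The false calls below therefore leave out the correlation between genes. Another 100 simulations of unchanged groups built each group from the deviations of its own 4 libraries. They carried the correlation between genes seen in those libraries. So few libraries can overstate it, so the extremes of these simulations may be too wide. Genes falsely called in both aged against young and aged HEP14 against aged, in opposite directions, averaged 314 and reached 7233 in these simulations. In aged against young, 62.7% of genes shifted by 2 SD and 89.4% of those shifted by 3 SD were recovered, with 235 false calls (1.3% of the unchanged genes). In HEP14 against vehicle in aged ovaries there were 333 false calls, and in aged against adult 339. In adult against young 56.7% of genes shifted by 2 SD were recovered with 15 false calls, and in adult HEP14 against adult 53.7% with 22. The aged group's scatter was larger than that of the others, and a common estimate of the spread makes the test too lenient where this group is compared and too strict where it is not. With 1 variance per group, the false calls were 88 in aged against young, 60 in aged HEP14 against aged and 56 in adult against young. Of genes shifted by 2 SD it recovered 34.3% in aged against young, 47.8% in aged HEP14 against aged (74.6% with the common estimate) and 88.1% in adult against young, so a call lost under it in the first 2 of these can also reflect lower recovery. That fit was an alternative added after seeing the data.

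No 2 libraries were identical, and the highest correlation across genes between any 2 was 0.766. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between libraries. Alternatives that could be run were a fit of only the compared groups, the replicate number as a block, library weights, robust moderation, an adjusted p of 0.01 and leaving out each library. Pseudocounts, low-value filters, median-of-ratios scaling, quantile normalization and a fold minimum could not be run on scores. Single values per library were compared with two-sided exact permutation tests, whose smallest p for 4 against 4 is 0.0286.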

Results

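Ovarian transcriptomes were compared across age and after HEP14, a small molecule that activates protein kinase C and promotes the formation of lysosomes. The design text frames the comparison around the effect of HEP14 on ovarian function in aged mice, and the series title names mitophagy (the removal of mitochondria by autophagy) and oxidative stress. Scores were available in 20 libraries, 4 per group, and the total reads behind them are not known. All values below are scores in SD of the gene, as mean ± SD with n = 4, and differences are given with their standard error.

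The 4 aged libraries lay apart from the other 16. On the first principal component, which held 46.7% of the variance, they took values from 135 to 200, and the group with the next highest values, aged with HEP14, lay between -39.3 and -9.58. The median SD within a group was 0.867 in aged ovaries, against 0.279 in young, 0.447 in adult, 0.424 in adult with HEP14 and 0.462 in aged with HEP14. More genes were at a tied lowest value in aged libraries (2895 ± 878.8, range 1956 to 3697) than in young libraries (864.2 ± 60.46), a difference with an exact permutation p of 0.0286 and an adjusted p of 0.0477 over 5 comparisons. HEP14-treated aged libraries had 985 ± 112.6 such genes, with the same exact permutation p of 0.0286 against aged libraries. All results that involve the aged group rest on these 4 libraries, and the library medians differed too, from -0.624 to -0.279 in aged libraries and from -0.159 to 0.018 in the others.

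**Figure D1:**
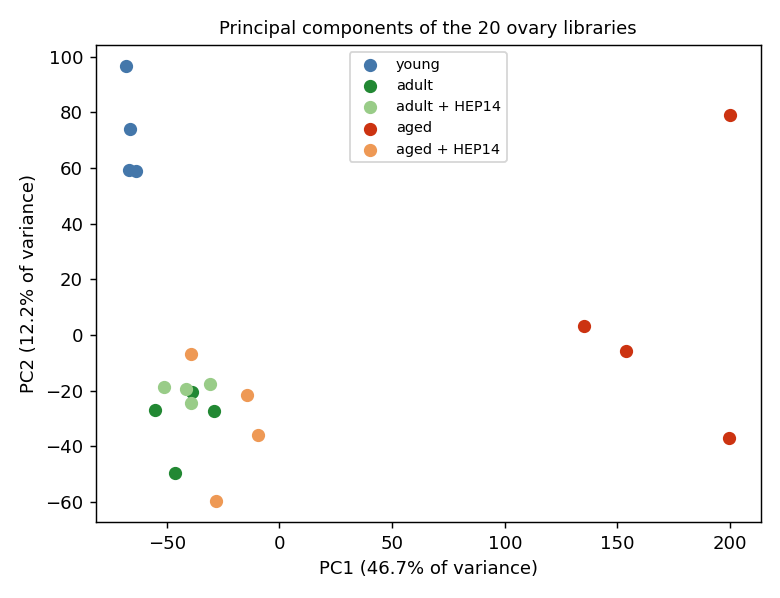
The first 2 principal components of the scores of all genes in the table, with 1 point per library coloured by group and the share of variance on each axis. The 4 aged libraries lie between 135 and 200 on the first component, and no other library lies above 0.

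**Figure D2:**
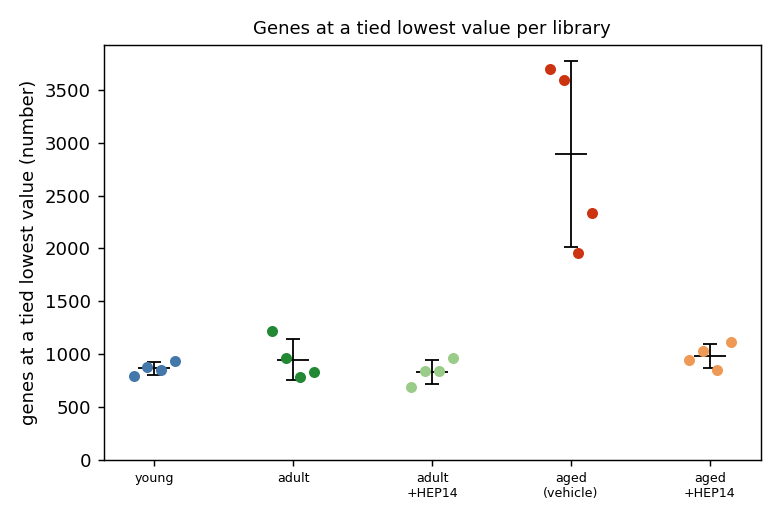
Number of genes at a lowest value shared by at least 2 libraries, with 1 point per library, a horizontal line for the group mean and bars for its SD (n = 4). The aged libraries range from 1956 to 3697 and the highest other library has 1218.

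The comparison of aged with young ovaries asked which transcripts differed between the ends of the age range. Transcripts of oocytes, dividing cells, ribosomes and extracellular matrix fell by camera at the preset correlation. Those of lymphocytes, antigen presentation and the mitochondrial genome rose by the same test. Of 25 oocyte genes, 23 were lower, among them Nlrp5, a maternal-effect gene (-1.66 ± 0.43 against 1.09 ± 0.35), and Gdf9, the oocyte growth factor that acts on granulosa cells, which differed by -2.70 (SE 0.34, adjusted p = 1.21e-06). Only 14 of the 25 had no tied lowest value, and tied values were more frequent in aged libraries. Zp3 of the egg coat differed by -2.63, and Amh, made by granulosa cells of growing follicles, by -2.50. Of 26 cell cycle genes 23 were lower, with the replication helicase subunits Mcm4 at -2.73 and Mcm6 at -2.90. Of 21 stroma and matrix genes 19 were lower, with the fibrillin gene Fbn1 at -2.73, Col1a1 at -2.55 and Col3a1 at -2.32, and of 30 ribosomal protein genes 24 were lower, with Rps3 at -2.75. All 13 mitochondrially encoded subunits of the respiratory chain were higher, with mt-Co1 at 1.84 ± 0.52 against -0.85 ± 0.08 and mt-Nd6 differing by 2.77. T and NK cell genes were higher in 15 of 16, led by the T cell receptor constant gene Trbc2 (2.84, SE 0.29, adjusted p = 1.76e-07). B and plasma cell genes were higher in 14 of 16, and antigen presentation genes in 13 of 14, including the peptide transporter Tap2 (2.68). These 8 lists passed camera, with adjusted p from 2.45e-06 for the mitochondrially encoded genes to 0.000684 for B and plasma cells, and an adjusted p of 0.756 for each with an estimated correlation. Adjusted over the list alone, 24 oocyte, 23 cell cycle, 20 matrix, 26 ribosomal, 13 mitochondrial, 15 T and NK cell, 16 B and plasma cell and 13 antigen presentation genes passed.

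Among single genes, the largest rises included Neat1, a long noncoding RNA of nuclear paraspeckles (chromosome 19, 5824708 to 5845478, minus strand), at 1.59 ± 0.28 against -1.35 ± 0.13 (ENSMUSG00000092274). Il18, an inflammatory cytokine (chromosome 9, 50554827 to 50581840, plus strand), differed by 2.92 (SE 0.31, adjusted p = 2.13e-07), and Mndal, Gimap3, Dusp11, Tomm34, Fam214b and the mitochondrial transfer RNA mt-Te by 2.87 to 2.90. The largest falls were those of Bpgm, which makes 2,3-bisphosphoglycerate (chromosome 6, 34476207 to 34505613, plus strand), at -1.61 ± 0.31 against 1.37 ± 0.21, and those of D10Wsu102e (-2.96) and Rhpn2 (-2.95). The imprinted noncoding RNA H19 (chromosome 7, 142575529 to 142578143, minus strand) was -1.47 ± 0.06 against 1.47 ± 0.06. The glycogen phosphorylase Pygb and Mageh1 each differed by -2.94, and the DNA damage sensor Parp1 and the germ cell gene Tdrd1 each by -2.93.

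Of the 24 mitophagy, lysosome, antioxidant and ovarian genes named beforehand, 3 were higher in aged ovaries, 13 were lower and 8 did not pass. Pink1, the kinase that marks damaged mitochondria (chromosome 4, 138313409 to 138326307, minus strand), was -1.79 ± 0.34 against 0.35 ± 0.34. The autophagy receptor Sqstm1 differed by -1.35 and Bnip3 by -1.40. Tfeb, a transcription factor of lysosome genes, was higher by 2.53 and the lysosome membrane gene Lamp1 was lower (-1.73). Nfe2l2, the regulator of antioxidant genes, and its target Nqo1 were lower (-1.50 and -2.23), as were Prkcd (-2.32) and the macrophage gene Adgre1 (-1.54), and Star of steroid synthesis was higher (1.39). Hmox1 (-0.65, adjusted p = 0.0688), Cat (-0.77, adjusted p = 0.0924), Gpx4 (-0.84), Prkca (-0.53), Cyp19a1 (-0.29), Ctsd (-0.10), Sod2 (0.30) and Cdkn1a (-0.00) did not pass. With 1 variance per group the calls of Star (adjusted p = 0.097) and Adgre1 (adjusted p = 0.121) were lost, and setting the library medians equal, or leaving out aged library 3 (adjusted p = 0.0566), also ended that of Adgre1. Without aged library 2, Cat passed (adjusted p = 0.0455).

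Other lists did not pass in this comparison, in which 74.32% of all genes were called. Higher and lower members numbered 7 and 18 of 29 for mitophagy and autophagy, 10 and 17 of 36 for lysosome, 3 and 14 of 27 for antioxidant genes and 4 and 6 of 12 for protein kinase C. They numbered 12 and 24 of 45 for the nuclear respiratory chain, 8 and 5 of 15 for mitochondrial biogenesis and dynamics, 5 and 11 of 20 for DNA repair and 4 and 11 of 18 for endoplasmic reticulum stress. For the ovarian cell types they were 1 and 10 of 17 for granulosa, 5 and 2 of 12 for theca, 7 and 1 of 10 for luteal, 1 and 4 of 12 for the ovulation response and 5 and 4 of 12 for surface epithelium genes. Without a single library some of these lists passed: granulosa without aged library 3 (adjusted p = 0.0282) or 4 (adjusted p = 0.0278), and luteal without young library 2 (adjusted p = 0.0399) or aged library 1 (adjusted p = 0.0463). For other tissues they were 0 and 7 of 11 for smooth muscle, 3 and 5 of 13 for endothelium, 0 and 9 of 16 for oviduct, 2 and 9 of 13 for adipose, 1 and 3 of 7 for blood and 8 and 2 of 18 for macrophage genes. With the library medians set equal, oviduct had 0 higher and 5 lower members and adipose 2 and 5. Smooth muscle passed without aged library 3 (adjusted p = 0.023) and oviduct without young library 4 (adjusted p = 0.0251). Interferon response genes were 7 and 2 of 17, senescence genes 4 and 2 of 15, cholesterol synthesis genes 8 and 2 of 20 and immediate early genes 7 and 0 of 14. In all, 13119 genes passed, 5833 higher and 7286 lower in aged ovaries, and with the library medians set equal 6574 were higher and 6313 lower. In 60.13% of the genes the 4 aged and 4 young libraries did not overlap, against 2.857% by chance.

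The comparison of adult with young ovaries covered the earlier age step. By camera at the preset correlation, genes of cholesterol and steroid synthesis rose, and genes of matrix, adipose tissue, oviduct and cell division fell. None of these lists passed with an estimated correlation. Of 26 cell cycle genes only 5 were called lower, and 3 with the library medians set equal. Of 20 cholesterol synthesis genes 15 were higher, with the sterol oxidase gene Msmo1 (chromosome 8, 64718139 to 64733792, minus strand) at 0.87 ± 0.57 against -1.27 ± 0.38 and Idi1 differing by 1.52. Luteal genes were higher in 7 of 10 and theca and steroidogenic genes in 7 of 12. They included the prostaglandin F receptor Ptgfr (2.40, SE 0.37, adjusted p = 0.00104), Sfrp4 (2.35), the lipoprotein receptor Scarb1 (2.24) and Cyp11a1, the enzyme that starts steroid synthesis (2.16). As 4 luteal and 5 theca and steroidogenic members were also in another list, the lists are not fully separate. Antioxidant genes were higher in 7 of 27 and lower in 1, with Hmox1 at 1.47 and Gpx3 at 1.89, and lysosome genes were higher in 6 of 36, with Atp6v0d2 at 2.22. Genes that fell included 10 of 13 adipose genes with 1 higher (Fabp4, -2.30, and Retn, -2.23), 7 of 16 oviduct genes (Ovgp1, -2.06, and Pax8, -1.99), 8 of 21 matrix genes (the elastin gene Eln, -2.22), 5 of 26 cell cycle genes (Mcm7, -1.98), 4 of 20 DNA repair genes (Msh6, -1.73), 3 of 25 oocyte genes (Lhx8, -1.44) and 3 of 30 ribosomal protein genes (Rpl18, -1.94). The adipose and oviduct lists are markers of tissue next to the ovary, and their mean scores in the young libraries spanned 0.13 to 1.98 and -0.28 to 2.31. The largest single differences also included Vps37a (2.35), Sgk1 (2.31), Evc2 (-2.43), Arsi (-2.40) and Klhl29 (-2.38).

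In adult against young ovaries 1751 genes passed, 486 higher and 1265 lower, and 18 of 31 lists passed camera, 11 higher and 7 lower. Lists with few called members also passed: macrophage (4 higher and 1 lower of 18), B and plasma cells (3 of 16 higher), antigen presentation (2 of 14), immediate early genes (2 of 14), T and NK cells (0 of 16) and the mitochondrially encoded genes, where 1 of 13 was lower although the median difference was 0.50. The 18 lists had an adjusted p of 0.0963 (luteal) to 0.547 with an estimated correlation, with 0.308 for cholesterol synthesis. Adjusted over the list alone, 17 cholesterol synthesis, 8 luteal, 8 theca, 11 antioxidant, 6 lysosome, 12 adipose, 15 oviduct, 14 matrix, 10 cell cycle, 4 DNA repair, 3 oocyte, 6 ribosomal and 8 macrophage genes passed. So did 3 B and plasma cell, 2 antigen presentation, 2 immediate early, 1 mitochondrially encoded and 0 T and NK cell genes. The count of genes moved with the treatment of the spread, to 3789 in a fit of the young and adult libraries alone and to 5174 with 1 variance per group. Without adult library 2 the ribosomal protein list (adjusted p = 0.067) and the immediate early list (adjusted p = 0.0589) did not pass, and the latter also not without adult library 4 (adjusted p = 0.0728). Smooth muscle passed without adult library 1 (adjusted p = 0.0353) and endothelium without adult library 3 (adjusted p = 0.0234). The count of genes fell to 628 without young library 1, 646 without adult library 2, 865 without young library 3 and 1074 without adult library 1. The call of Lhx8 ended without any library but young 2 and adult 3 (adjusted p = 0.0509 to 0.091). Leaving out young library 1 ended those of Gpx3 (adjusted p = 0.0575) and Ovgp1 (adjusted p = 0.0529), and leaving out adult library 2 those of Gpx3 (adjusted p = 0.0671), Mcm7 (adjusted p = 0.0522) and the mitochondrially encoded mt-Nd3 (adjusted p = 0.0519).

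From adult to aged ovaries, the later age step, mitochondrially encoded, lymphocyte and antigen presentation genes rose by camera at the preset correlation. Oocyte, antioxidant, cell cycle and ribosomal protein genes fell by the same test. All 13 mitochondrially encoded genes were higher, with mt-Nd3 at 1.65 ± 0.48 against -0.78 ± 0.15. Of 27 antioxidant genes 16 were lower and 2 higher, led by the thioredoxin reductase gene Txnrd1 (-1.87 ± 0.34 against 0.57 ± 0.23) and the glutathione peroxidase gene Gpx1 (-2.46, SE 0.29, adjusted p = 9.42e-07). Oocyte genes were lower in 20 of 25, cell cycle genes in 19 of 26 and ribosomal protein genes in 21 of 30. T and NK cell genes were higher in 14 of 16, B and plasma cell genes in 13 of 16 (the light chain gene Iglc2, 2.27) and antigen presentation genes in 9 of 14. The 8 lists had camera adjusted p from 5.95e-06 to 0.0249, and an adjusted p of 0.83 (antioxidant and mitochondrially encoded) or 0.857 (the other 6) with an estimated correlation. Adjusted over the list alone, 13 mitochondrial, 18 antioxidant, 22 oocyte, 20 cell cycle, 24 ribosomal, 15 T and NK cell, 14 B and plasma cell and 9 antigen presentation genes passed. Leading single genes were Lsp1 (2.67), Htra2 and Kri1 (2.66), Zcwpw1 (2.64), Lztfl1 (-2.68), Ubxn6 and Ccni (-2.64) and Gpd2 (-2.63). The antigen presentation list lost its call without adult library 3 (adjusted p = 0.075), aged library 1 (adjusted p = 0.0685) or aged library 4 (adjusted p = 0.0752). Lists that passed without a single library were interferon response (adult library 1 or 4 or aged library 3; adjusted p = 0.0174, 0.0217 and 0.0335), granulosa (aged library 3 or 4; adjusted p = 0.0359 and 0.0424), lysosome (adult library 3 or aged library 1; adjusted p = 0.0226 and 0.00753) and cholesterol synthesis (aged library 2; adjusted p = 0.00879). In all, 11789 genes passed, 5486 higher and 6303 lower, and with the library medians set equal 6157 were higher and 5231 lower.

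The comparison that the series centres on set aged ovaries with HEP14 against aged ovaries with vehicle. Antioxidant, ribosomal protein, cell cycle and oocyte genes were higher with HEP14 by camera at the preset correlation. Mitochondrially encoded and T and NK cell genes were lower by the same test. Lysosome, granulosa and B and plasma cell lists also passed, but with calls that single libraries decided. Of 27 antioxidant genes 18 were higher and 1 lower. Gpx1 (chromosome 9, 108338903 to 108340343, plus strand) was 0.51 ± 0.49 against -1.82 ± 0.25, and the mitochondrial peroxiredoxin gene Prdx3 (chromosome 19, 60864051 to 60874556, minus strand) was 0.72 ± 0.58 against -1.75 ± 0.11. Cat, which encodes catalase, differed by 2.31, Hmox1 by 1.92 and Nfe2l2 by 1.81. Of 36 lysosome genes 22 were higher and 8 lower, with Lamp1 (chromosome 8, 13159161 to 13175338, plus strand) at 0.58 ± 0.24 against -1.78 ± 0.72 and the cholesterol transporter gene Npc2 at 2.39. The lysosome list lost its call without aged library 3 (adjusted p = 0.102) or 4 (adjusted p = 0.0938), or HEP14-treated aged library 2 (adjusted p = 0.0568) or 4 (adjusted p = 0.0707). Of 29 mitophagy and autophagy genes 16 were higher and 7 lower. That list did not pass camera (adjusted p = 0.135; adjusted p = 0.825 with an estimated correlation), and fry, which asks whether members move on balance one way, gave an adjusted p of 1.83e-05. The fry test does not compare members with other genes. Here 62.5% of all genes were called and 18 of 31 lists passed fry, so it does not set this list apart. Pink1 was 0.24 ± 0.43 against -1.79 ± 0.34, Sqstm1 differed by 2.32 and Bnip3 by 2.15, and Tfeb (-1.53) was lower with HEP14. All 13 mitochondrially encoded genes were lower, with mt-Nd3 at -2.42 (SE 0.30, adjusted p = 2.66e-06).

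Ovarian and immune genes differed as well between HEP14 and vehicle in aged mice. Oocyte genes were higher in 16 of 25 and lower in 1, with Gdf9 at -0.09 ± 0.51 against -1.62 ± 0.79, Zp3 at 1.43 and Nlrp14 at 1.67, while Tle6, a maternal-effect gene, was lower (-2.13). Only 14 of the 25 oocyte genes had no tied lowest value. The mean score of the oocyte list was 0.437 and 0.164 in HEP14-treated aged libraries 1 and 2, while library 3 (-0.876) lay within the aged range of -1.689 to -0.725 and library 4 (-0.599) just above it. Granulosa genes were higher in 12 of 17 (Kitl, 1.94) and lower in 1 (Greb1, -1.96), and Amh was higher (1.84). The granulosa list's mean score was low in aged libraries 1 and 2 (-1.927 and -1.897), which had the most genes at a tied lowest value, and not in aged libraries 3 and 4 (-0.004 and 0.015), against 0.143 to 0.610 with HEP14. Its call ended without aged library 1 (adjusted p = 0.101) or 2 (adjusted p = 0.0837) or HEP14-treated aged library 1 (adjusted p = 0.0786) or 2 (adjusted p = 0.0649), and had an adjusted p of 0.505 without both aged libraries 1 and 2. With the library medians set equal 8 granulosa genes were higher. Cell cycle genes were higher in 17 of 26 (Mcm4 and Pcna, both 2.17) and ribosomal protein genes in 22 of 30 (Rpl7, 2.27). T and NK cell genes were lower in 13 of 16 (Cd2, -2.16) and B and plasma cell genes in 12 of 16, a list that did not pass without aged library 4 (adjusted p = 0.0723). The 9 lists had camera adjusted p from 1.79e-06 to 0.0414, and 0 passed with an estimated correlation, where their adjusted p was 0.525 for antioxidant genes, 0.702 for mitochondrially encoded genes and 0.825 for the other 7. Adjusted over the list alone, 19 antioxidant, 30 lysosome, 13 mitochondrial, 17 oocyte, 13 granulosa, 19 cell cycle, 23 ribosomal, 14 T and NK cell and 14 B and plasma cell genes passed, and 23 mitophagy and autophagy genes. Some lists that did not pass did so without certain libraries: antigen presentation (8 of 14 lower) without aged library 2 or 3 or HEP14-treated library 3 (adjusted p = 0.0332, 0.0131 and 0.0363), and interferon response (10 of 17 lower) without aged library 3 or HEP14-treated library 3 (adjusted p = 0.0321 and 0.047). The nuclear respiratory chain (20 of 45 higher and 6 lower; adjusted p = 0.0136 and 0.00422) and cholesterol synthesis (7 of 20 higher; adjusted p = 0.0108 and 0.0282) passed without aged library 2 or HEP14-treated library 3, and without both aged libraries 1 and 2 (adjusted p = 0.00984 and 0.00948). Col1a1 (0.81, adjusted p = 0.0935), Col3a1 (0.16), Star (0.68), Cyp19a1 (adjusted p = 0.198), Sod2 (0.94), Adgre1 (0.12) and Cdkn1a (0.05) did not pass. Nqo1 (1.32), Prkcd (1.31) and Gpx4 (1.83) passed but not with 1 variance per group (adjusted p = 0.122, 0.134 and 0.0679), and with the library medians set equal the calls of Nqo1 (0.95) and Prkcd (0.94) were also lost, while Prkca (1.72) and Ctsd (1.73) also passed. Single libraries decided some of these: without aged library 1 Nqo1 (adjusted p = 0.132) and Prkcd (adjusted p = 0.123) lost their calls and Col1a1 passed (adjusted p = 0.0421). Nqo1 also lost its call without HEP14-treated aged library 1 or 3 (adjusted p = 0.0702 and 0.0733), and Prkcd without aged library 2 (adjusted p = 0.0554) or HEP14-treated aged library 1 or 2 (adjusted p = 0.0677 and 0.0762). Sod2 (adjusted p = 0.0417) and Star (adjusted p = 0.0456) passed without aged library 2, and Cyp19a1 (adjusted p = 0.0341) without aged library 4.

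The genes with the largest differences were Plpp1, a lipid phosphatase gene (2.74, SE 0.33, adjusted p = 2.4e-06), Ly6c1 (2.68), Gnas of the stimulatory G protein (2.68), Tob2 and the DNA end-joining gene Xrcc4 (both 2.67), Elk1 (2.63), Tspan31 (2.62) and Msl3l2 (2.59). Those lower with HEP14 were Commd3 (-1.23 ± 0.42 against 1.52 ± 0.44), Ddx50 (-2.67), the splicing kinase gene Srpk1 and Diexf (both -2.62), Nrf1, a transcription factor of nuclear respiratory genes (-2.61), Anapc2 (-2.60), Akap17b and Ftsj3 (both -2.57). In all, 11031 genes passed, 5859 higher and 5172 lower with HEP14. The larger side turned with the library medians set equal (4639 higher and 5965 lower) and without aged libraries 1 and 2 (4888 higher and 5039 lower).

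**Figure D3:**
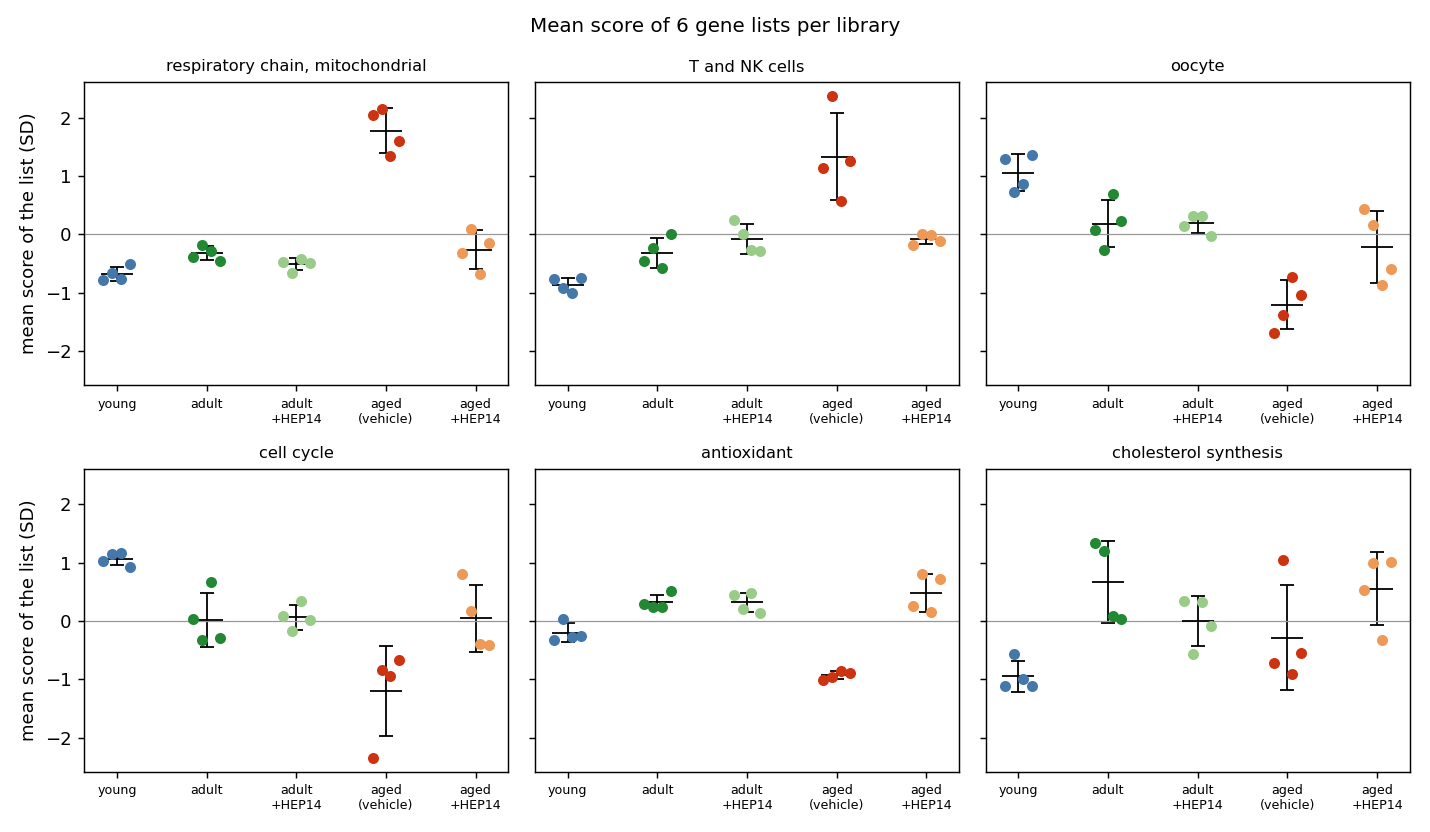
Mean score, in SD, of the members of 6 gene lists, with 1 point per library, a horizontal line for the group mean and bars for its SD (n = 4). The mitochondrially encoded list lies at 1.34 to 2.15 in aged libraries and at -0.68 to 0.09 in aged libraries with HEP14.

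The calls for HEP14 in aged ovaries ran against those for age. Of the 13119 genes called in aged against young, 9748 (74.3%) were called in the opposite direction with HEP14 and 19 in the same direction. Independent lists of these sizes would give 4128 opposite calls, and 100 simulations of unchanged groups that share the aged libraries gave 314 on average and 7233 at most. The correlation across genes, which are not independent replicates, was r = -0.866 (rho = -0.821) against a simulated mean of -0.702. The most negative simulated r was -0.961, so the observed r lay within what unchanged groups gave. The covariance was -2.47, against -0.275 on average and -1.34 at the most negative. When the aged libraries were split so that each comparison used 2 of them, the 6 splits gave 7209 to 7760 opposite calls and r from -0.725 to -0.66. With adult in place of young, and without a split, there were 10365 opposite calls. A feature shared by all aged libraries given vehicle would enter both comparisons with opposite sign, with or without a split. The splits remove only the noise of single libraries that both comparisons share. Opposite calls therefore cannot separate a reversal of age changes by HEP14 from such a feature.

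The comparison of HEP14 with control in adult ovaries addressed the same treatment at a younger age. A single gene passed, the sense-intronic RNA Gm38115 (chromosome 1, 36913601 to 36916539, minus strand; 1.77 ± 0.72 against -0.53 ± 0.00, adjusted p = 0.0284), which lay outside the naming rule, was chosen after its values were seen and was at a tied lowest value in 15 libraries. In limma 345 genes had an unadjusted p under 0.05, and 1.428% of genes had no overlap between the groups, against 2.857% by chance. The median half-width of the 95% interval of a difference was 0.982 SD, and for 95% of genes the interval lay within 2 SD of 0. The camera test called 12 lists, among them cholesterol synthesis (lower; median -0.69), ribosomal proteins (higher; 0.52) and macrophage genes (higher; 0.66), but no member of any of them passed. Their adjusted p with an estimated correlation was 0.395, 0.596 and 0.395, and fry gave an adjusted p of 0.828 for each. Members with the smallest p were Idi1 (-0.60), Sqle (-0.81), Rps14 (0.65), Rpl18 (0.72), Fcer1g (0.95) and C1qb (1.06). The other 9 lists were the ovulation response, stroma and matrix, endothelium, T and NK cells, antigen presentation, senescence, endoplasmic reticulum stress and both respiratory chain lists. Endothelium and mitochondrially encoded genes were on the lower side and the rest on the higher side, with an adjusted p of 0.395 to 0.62 with an estimated correlation, and adjusted over the list alone 0 members of the 12 lists passed. Of the 12 lists, all but macrophage and cholesterol synthesis lost their call without some single library, with ribosomal proteins at an adjusted p of 0.119 without adult library 2. Without HEP14-treated adult library 4, 4 genes and 6 lists passed, and without adult library 1, 2 or 3 or HEP14-treated adult library 1, 2 or 3, 0 genes.

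Whether HEP14 differences depended on age was tested with the interaction. The HEP14 difference in aged ovaries lay above that in adult ovaries for 4389 genes and below it for 3955, 8344 in all. With the aged labels kept, 16 of the 70 assignments of the 8 adult libraries to HEP14 and control gave at least as many genes, the real one included. It was higher for the ciliary trafficking gene Lztfl1 (chromosome 9, 123694416 to 123717697, minus strand; 3.10, SE 0.48, adjusted p = 0.000257), Arhgap18 (3.11), Mmp15 (3.09) and Usp22 (3.08). It was lower for Foxa3 (-3.22), Stx2 (-3.20), Tmsb4x (-3.14) and Mta2 (-3.10). By camera 11 lists passed, including antioxidant genes (15 of 27 higher; Prdx3, 2.78, and Prdx1, 2.56), cholesterol synthesis (9 of 20 higher; Idi1, 2.78), mitochondrially encoded genes (12 of 13 lower; mt-Nd3, -2.70) and T and NK cell genes (11 of 16 lower; Trbc1, -2.21). The others were oocyte (13 of 25 higher), granulosa (9 of 17), lysosome (17 of 36, with 6 lower), cell cycle (14 of 26) and ribosomal protein genes (13 of 30), and B and plasma cell (5 of 16 lower) and antigen presentation genes (6 of 14). With an estimated correlation the adjusted p was 0.599 for antioxidant genes and 0.786 for the other 10. Adjusted over the list alone, 15 antioxidant, 9 cholesterol synthesis, 12 mitochondrial, 13 T and NK cell, 14 oocyte, 10 granulosa, 25 lysosome, 14 cell cycle, 15 ribosomal, 2 B and plasma cell and 6 antigen presentation genes passed. Without aged library 4, 7 lists passed. The antioxidant, cholesterol synthesis, mitochondrially encoded, T and NK cell and cell cycle lists passed without each single library, and the other 6 lost their call without at least 1. Their highest adjusted p was 0.0515 for oocyte (without HEP14-treated aged library 1), 0.0945 for granulosa (without aged library 1), 0.109 for lysosome (without aged library 3), 0.116 for ribosomal protein (without adult library 4), 0.129 for B and plasma cell (without aged library 4) and 0.0771 for antigen presentation genes (without adult library 3). Interferon response passed without adult library 1 (adjusted p = 0.0351) or 4 (adjusted p = 0.0446), and the nuclear respiratory chain without HEP14-treated aged library 3 (adjusted p = 0.0447). With the library medians set equal, higher members numbered 8 for oocyte, 2 for granulosa, 8 for cell cycle, 6 for ribosomal protein, 6 for cholesterol synthesis, 12 for antioxidant and 12 for lysosome genes, and 8 B and plasma cell genes were lower. Of the called genes 52.6% were in the higher direction, and 40.6% with the library medians set equal. Across genes, the HEP14 differences at the 2 ages had r = -0.0942 (rho = -0.106), and 41 of 100 relabellings gave an r as large in size.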

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

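The tests of starting molecules, of relative depth, of the young to adult change and of the nuclear respiratory chain, and the comparison of HEP14-treated aged ovaries with adult groups, were chosen after related values had been seen. The tests of transcript length and GC content, of noncoding mitochondrial transcripts, of the HEP14 correlation and of other splits were set beforehand, except for the assignments of the adult libraries alone, which were added after the interaction count was seen.

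The HEP14 difference differed between ages in 8344 genes by the interaction test. Of 100 relabellings 1, the real one, gave as many. The highest other gave 7783, and it kept the aged groups as labelled and mixed the adult ones. Relabellings that mixed the aged groups gave 0 at most. The count therefore concerns the aged groups and, as with the splits below, does not exclude chance there. With the aged labels kept, 16 of 70 assignments of the adult libraries, the real one included, gave at least 8344 genes (the others 7588 to 9018), so the count does not single out the real adult labels. For aged against young 13119 genes passed, and the highest of the other splits gave 0 (1 of 35 splits as large). The highest other was also 0 for aged against adult (11789) and for aged HEP14 against aged (11031). These results do not exclude chance. The other splits mix the more scattered aged libraries into both groups, which can lower their counts. Simulated unchanged groups gave up to 7233 genes called in opposite directions in aged against young and aged HEP14 against aged. Chance can be excluded for adult against young (1751, highest other 1, 1 of 35 splits as large). It cannot be excluded for adult HEP14 against adult, where 7 of 35 splits gave at least the 1 real call. The highest of these gave 15. The genes in the table may have been picked for differing between the 5 groups (72.1% had an F test p under 0.05). Such a choice would favour the real grouping over other splits, so the exclusion holds only if they were not.

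The first pattern is that the aged libraries stand apart from the other 16. The values do not decide on a lower sequencing depth. The limit set by 1 read was poorly marked in aged libraries 1, 2 and 4, and total reads are not known. The lowest relative depth of an aged library was 0.791, in library 3 (peak of 197 genes, next highest 98). Less marked peaks gave 0.854 and 0.878 in aged libraries 1 and 2 (15 and 20 genes). That of aged library 4 gave 0.99 (85 genes, next highest 58). Few starting RNA molecules stay open: 1103 genes were at a tied lowest value in some aged library and above all 16 other libraries in another, against at most 169 in any other group, but as a share of the genes tied in some library of the group this was 26.4% of 4177 against 8.96% of 1886, and differences between aged mice could give the same, so the values do not decide it. The values cannot decide on GC content (Spearman's rho across protein-coding genes of 0.201 with the aged minus young difference, 0.297 with aged minus adult and -0.237 with aged HEP14 minus aged; -0.0448 for length in aged minus young) or on a continuation of the young to adult change (r = 0.0492 across genes, without shared libraries; 19 of 35 splits as large). A biological effect of age stays open.

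The second pattern is the higher score of all 13 mitochondrially encoded respiratory chain genes in aged ovaries, and their lower score with HEP14. A rise in the scores of most nuclear members of the chain is argued against. In aged ovaries 24 of them were lower and 12 higher (20 and 12 with the library medians set equal). Of all called genes 44.5% were higher (51% with equal medians), and levels of RNA are not known. The nuclear list did not pass as a whole (adjusted p = 0.18), and a rise of some members stays open. A larger mitochondrial share of the RNA remains a candidate explanation, since 16 of 18 noncoding mitochondrial transcripts, both ribosomal RNAs included, were also higher. Whether such a share would come from the tissue or from RNA handling was not tested.

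The third pattern is that HEP14 gave 11031 calls in aged ovaries and 1 in adult ovaries. The position of the aged vehicle libraries alone may account for it: aged ovaries with HEP14 differed from adult ovaries in 1 gene and from adult ovaries with HEP14 in 2, while vehicle-treated aged ovaries differed from adult in 11789. The common estimate of the spread is too strict for the first 2 counts and too lenient for the last. The first 2 were not repeated with 1 variance per group. The groups did not overlap in 3.156% and 4.991% of genes in the first 2, and in 49.56% in the last, against 2.857% by chance. These values do not separate an effect of HEP14 from a feature of the 4 vehicle libraries, since no other aged vehicle libraries exist here. Whether a HEP14 change is shared by both ages stays open at r = -0.0942, because relabellings ranged from -0.287 to 0.293 and would hide a small shared change. The bound set beforehand took a value within the central part of the relabellings as evidence against sharing, and was wrong for this reason.

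In 29 of 587 groups of 4 libraries a library lay far from the others, as the gap to its nearest neighbour over the range of the group, and chance gives about 29.4. Young library 2 had 8 of these and HEP14-treated adult library 4 had 5. In young ovaries the ratio was 0.849 for mt-Te, 0.92 for Bpgm, 0.841 for Pygb, 0.925 for Sparc, 0.859 for Hmox1, 0.925 for Sfrp4, 0.939 for Sgk1, 0.905 for Evc2, 0.84 for Figla, 0.863 for Rpl18 and 0.843 for the lysosome list. In adult ovaries it was 0.834 for Igha, 0.891 for Gpx1 and 0.883 for the surface epithelium list. In adult ovaries with HEP14 it was 0.918 for Ereg, 0.984 for Tek, 0.877 for mt-Nd4l, 0.943 for Tle6, 0.862 for Mcm4, 0.835 for the antigen presentation list and 0.855 for the immediate early list. In aged ovaries it was 0.908 for Mcm6, 0.895 for Bnip3, 0.851 for Tfeb, 0.868 for Npc2, 0.889 for mt-Atp6 and 0.835 for the cell cycle list, and in aged ovaries with HEP14 it was 0.965 for the oviduct list and 0.847 for the DNA repair list.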

How the results depend on the processing

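Group weights, genes without a tied lowest value, equal library medians, a minimum of 1 SD, unmoderated statistics and leaving out aged libraries 1 and 2 were chosen after seeing the data. The counts for aged against young (10341 to 13106 under the alternatives run), aged against adult (9041 at the lowest) and aged HEP14 against aged (8175 at the lowest) stayed within 1.5 times, as did the opposite calls (7393 at the lowest), and the correlation of HEP14 differences stayed between -0.138 and -0.0216. The count for adult against young (1751) moved to 3789 with only those groups, 6367 with library weights, 5174 with group weights, 376 at an adjusted p of 0.01, 784 without tied genes and 3618 without aged libraries 1 and 2, and ranged from 628 to 1475 without single libraries. The 1 call for adult HEP14 became 2 with library weights and 0 with only those groups, with the replicate block, at an adjusted p of 0.01, without tied genes and without aged libraries 1 and 2 (345 genes at an unadjusted p under 0.05 in limma), and ranged from 0 to 4 without single libraries. The interaction gave 5428 at an adjusted p of 0.01. With an estimated correlation 0 lists passed in all 6 comparisons, and with fry 24 passed in aged against young, 11 in adult against young, 18 in aged against adult, 18 in aged HEP14 against aged, 0 in adult HEP14 against adult and 5 in the interaction. Without single libraries 6 to 12 lists passed for adult HEP14 against adult and 7 to 12 for the interaction. A stricter threshold and fewer genes lower a count by construction, and otherwise the cause was not tested. Replicate numbers showed little pairing of the libraries. Correlations of deviations between libraries of the same number ran from -0.188 to 0.155 over the comparisons, with means from 0.00536 to 0.0419. A weak pairing is not excluded. With the replicate block 13106 genes passed in aged against young and 10965 in aged HEP14 against aged. Of 2104 values of named genes without single libraries, 66 lost their call, 5 gained it and 0 turned. Not run, because scores hold no levels, were other pseudocounts, low-value filters, median-of-ratios scaling, quantile normalization and a fold minimum, and limits from depth are not known for the same reason.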

Other observations

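The comparisons of HEP14-treated aged ovaries with other groups than aged vehicle, and the hypothesis below, were chosen after the data had been seen. HEP14-treated aged ovaries differed from young ovaries in 2798 genes, 950 higher and 1848 lower. Chance can be excluded for that count (1 of 35 splits as large; highest other 574) if the genes in the table were not picked for differing between the groups. They differed from adult ovaries in 1 gene (640 at an unadjusted p under 0.05 in limma) and from HEP14-treated adult ovaries in 2 genes (1082), counts that chance can give, since 7 and 3 of 35 splits were as large, with 10 and 2 as the highest others. The median 95% interval of a difference reached 0.982 SD to either side in both, so smaller differences are not excluded. These genes were named after their values were seen. Hapln1, which encodes a link protein of the hyaluronan matrix (chromosome 13, 89539796 to 89611652, plus strand), was called in both comparisons. It was 1.73 ± 0.62 in aged ovaries with HEP14, against -0.63 ± 0.10 in adult (adjusted p = 0.00787) and -0.40 ± 0.31 in adult with HEP14 (adjusted p = 0.0168). The pseudogene Gm46578 was lower in aged ovaries with HEP14 than in adult ovaries with HEP14 (-2.36).

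Tfeb and the lysosome gene Lamp1 moved apart. In aged against young ovaries Tfeb differed by 2.53 and Lamp1 by -1.73, and with HEP14 in aged ovaries by -1.53 and 2.36. In the lysosome list the members called in aged ovaries with HEP14 went both ways, 22 higher and 8 lower.

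A hypothesis that the young to adult change continues with age in HEP14-treated mice was tested with the correlation across genes of adult minus young with aged HEP14 minus adult HEP14, which share no libraries. The value was r = 0.125 (rho = 0.151), and 14 of 35 splits of the young and adult libraries gave an r as large in size, up to 0.292, so the values cannot decide it.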
